A study of Homo sapiens with 24 samples.

How the data were processed

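Messenger RNA was measured in skeletal muscle of 24 patients with elective abdominal surgery, 8 nonobese, 8 obese and 8 morbidly obese, on Affymetrix arrays. The groups are those of the submitted sample labels, 1 array per sample. The labels do not say that the 24 patients are different people, so p-values measure only the spread between these samples.

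The deposited values are linear signal intensities, all above 0. The mean after trimming 2% at each end was close to 800.2 on every array, from which a scaling of each array to a common level was inferred. The software and the method behind the intensities are not given in the sources used here, and detection calls were not used here, so that the signal over background of a probe set is not known. As for any array study, the number of arrays limits the precision.

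The table held 22283 probe sets. Of these, 19003 carried a single gene symbol, 1043 several and 2107 none, and 68 were control probe sets. Sex-linked genes (62 probe sets) were left out of every analysis. Probe sets with several symbols or none were not named or used in the gene results. Tested apart with limma, 657 with several and 964 with none above the filter gave 0 calls in each comparison, with 84, 81 and 30 and with 77, 81 and 26 at an unadjusted p under 0.05. Values were taken as log2(value + 16) with the deposited scaling kept, and each of 11925 genes was represented by its probe set with the highest mean. Genes with a mean log2 level under 7.91, the 40th percentile of all probe sets, were removed, which left 8180. No coordinates are given, since the array annotation names no genome build.

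Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), in 1 fit of the 3 group means with 21 residual degrees of freedom. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. A log2 difference is the first group minus the second, and SE is limma's standard error. The F test of the 3 groups came from the same fit. The overlap of the contrasts against nonobese was compared with 100 draws of unchanged groups. Correlations across samples had 100000 permutations.

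Before the data were examined, 35 lists with 714 genes were fixed for lipid and energy metabolism, fibre types, stress, immune response and cell types, of which 614 genes had a probe set. A list needed at least 5 tested genes, which 33 lists had. Markers of red blood cells (4 tested genes) and of nerve (3) were not tested as lists. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and by an exact two-sided permutation test of the list mean per sample over all 12870 splits of 8 against 8. A separate list held 25 genes of fatty acid partitioning. The rule for named genes was also fixed then. It takes up to 12 called genes in each direction by size of the difference. Where fewer than 10 genes are called, it takes the 10 higher and 10 lower genes with the smallest p, said not to have passed. It adds the measured genes of fatty acid partitioning and up to 4 members with the smallest p of each list described.

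The alternatives concerned the pseudocount, the filter, quantile normalization, the choice of probe set, the groups in the fit, array weights, robust variance, the title numbers as a block, covariates, sample titles with another suffix, and leaving out each of the 24 samples. After the data were seen, 5 alternatives on the array ceiling and on abundant genes were added.

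The gene test was tested on simulated data in which 67, 67 and 66 of the 8180 genes were changed by 0.5, 1 and 2 on the log2 scale. It recovered 32.8%, 83.6% and 98.5% for morbidly obese against nonobese, 41.8%, 88.1% and 100% for obese against nonobese, and 59.7%, 88.1% and 98.5% for morbidly obese against obese. It called 0.1%, 0.063% and 0.13% of unchanged genes. With no gene changed, 0%, 20% and 10% of 20 simulations called any gene. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.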

Results

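Gene expression was profiled in skeletal muscle from people who had elective abdominal surgery, using Affymetrix oligonucleotide arrays on which each gene is read by 1 or more probe sets. The 24 samples formed 3 groups of 8, described by the submitters as nonobese, obese and morbidly obese. The title of the series names obesity and the oxidation of fatty acids, so the 3 pairwise comparisons ask how muscle transcripts, above all those of fatty acid handling, differ with the degree of obesity. Each array held 22283 probe sets. The trimmed mean signal lay between 800.2 and 800.3 on every array and the median signal between 322 and 371. Any pair of samples correlated between 0.875 and 0.954 across the 8180 genes tested. The number of arrays limits the precision of every value.

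The brightest signals differed between the groups. The array ceiling, defined here as the log2 of the signal that 0.1% of an array's probe sets exceed, was 14.35 ± 0.35 in nonobese, 13.93 ± 0.28 in obese and 13.93 ± 0.31 in morbidly obese samples (SD, n = 8 each). It was lower than in nonobese by 0.42 in both obese groups, with exact two-sided permutation p = 0.023 for obese and p = 0.026 for morbidly obese, each 0.121 after adjustment over 12 comparisons of technical measures. The obese groups themselves did not separate on it (exact permutation p = 0.989). Of the 12 arrays with the higher ceiling, 7 were nonobese, 2 obese and 3 morbidly obese. Within each group these were the lowest title numbers, 1 to 7 in nonobese, 1 and 2 in obese and 1 to 3 in morbidly obese samples. The labels do not say what the numbers mean, and a change with the order of processing was not tested. Across the 24 arrays the ceiling followed the first principal component of expression, which held 15.1% of the variance, with r = 0.983 and rho = 0.971 (permutation p = 1e-05 each, the smallest the 100000 permutations can give, 2e-05 after adjustment over 8 relations). That correlation was 0.982 without the 2 arrays farthest from the median ceiling, 0.936 among the arrays of the higher 12 and 0.909 among the lower 12. Values with the ceiling as a covariate, an alternative chosen after seeing the data, are given below beside the gene groups that moved with it.

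Morbidly obese muscle was first set against nonobese muscle. Transcripts of contractile proteins, cytosolic ribosomal proteins and respiratory complexes II to IV had lower signals in the morbidly obese group, and those of the proteasome and of macrophages had higher signals, as judged by the test of gene lists with a preset correlation. None of these lists passed with an estimated correlation (lowest adjusted p = 0.402), and none of them passed with the array ceiling as a covariate. Among single genes, the smallest p belonged to NNMT, which methylates nicotinamide. Its log2 signal was 9.92 ± 0.66 in morbidly obese against 11.1 ± 0.68 in nonobese samples (SD, n = 8), a fold of 0.437 (log2 difference −1.20, SE 0.27), and 7 of 8 morbidly obese samples lay below the nonobese mean. Both NNMT probe sets had lower signals, by −1.20 and −1.32. No gene passed the threshold in limma's test with Benjamini-Hochberg adjustment. The count of genes called was 0 of 8180, the lowest adjusted p was 0.451, and 610 genes had an unadjusted p under 0.05, 345 higher and 265 lower, where chance alone gives 409. With the array ceiling as a covariate 400 genes had such a p, 189 higher and 211 lower.

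None of the following 20 genes passed the adjustment. The 10 with the smallest p among higher signals had log2 differences of 0.48 for CEP162, a centriolar protein, 0.42 for NDUFAF1, an assembly factor of respiratory complex I, 1.01 for the deubiquitinase MINDY3, 1.08 for MPDU1, 0.47 for vinculin (VCL), 0.44 for SAR1B, a GTPase of vesicle transport, 0.39 for ARPC5L, 0.56 for CEACAM4, 0.39 for CACYBP and 0.52 for the nucleoside transporter SLC29A2. All 8 morbidly obese samples exceeded the nonobese mean for each of these 10. Another probe set of CEP162, under the filter level, differed by −0.74. The others of CACYBP differed by 0.03, 0.08 and 0.11, and that of VCL by 0.73. The 10 with lower signals were, besides NNMT, beta-actin (ACTB) at −0.54, the transcriptional repressor BCL6 at −0.60, vimentin (VIM) at −0.45, MRPL33 at −0.93, the fast troponin C TNNC2 at −2.68 (SE 0.73), PTPN3 at −0.61, KALRN at −0.51, RAB15 at −0.46 and BLTP1 at −0.65. Adjusted for the ceiling, the differences of ACTB, BCL6, MRPL33 and TNNC2 shrank to −0.26, −0.31, −0.41 and −1.03, while that of NNMT was −1.4998. Another probe set of KALRN, under the filter level, differed by 0.42, while the others of ACTB, BCL6, RAB15 and BLTP1 were lower too.

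Of 33 gene lists tested with camera, 6 passed at an adjusted p under 0.05 with the preset inter-gene correlation, 4 lower and 2 higher in morbidly obese muscle. An exact permutation test of the list mean per sample passed none after adjustment (lowest adjusted p = 0.498). In the cytosolic ribosome list, 40 of 41 measured genes had lower signals, with a mean log2 difference of −0.49 (adjusted p = 6.0e-30, and adjusted p = 0.402 with an estimated correlation). RPL37 differed by −0.40, RPS7 by −0.34, RPL18 by −0.41 and RPL10A by −0.32, and 27 members passed when adjusted over the list alone against 0 over all genes. All 11 slow fibre genes had lower signals, by −1.06 on average (adjusted p = 1.3e-06, and adjusted p = 0.436 with an estimated correlation). They included myoglobin (MB) at −3.89, the slow troponin I TNNI1 at −0.54, the slow myosin heavy chain MYH7 at −1.18 and the calcium pump ATP2A2 at −1.16. Of 13 fast fibre genes, 10 had lower signals, averaging −0.82 over the list (adjusted p = 4.4e-04, and adjusted p = 0.466 with an estimated correlation). TNNC2 passed when adjusted over that list alone, and TNNT3 differed by −0.53, CASQ1 by −0.48 and ATP2A1 by −3.22. Among 23 genes of complexes II to IV, 17 had lower signals, including the cytochrome c oxidase subunits COX8A at −0.90, COX5B at −0.43 and COX7A1 at −0.78, while SDHC of complex II differed by 0.34. The mean was −0.24 (adjusted p = 5.5e-05, and adjusted p = 0.757 with an estimated correlation), and −0.01 under quantile normalization.

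The first 3 of these lists followed the array ceiling, and the relation was not computed for complexes II to IV. Across the 24 arrays the list mean correlated with the ceiling at r = 0.989 and rho = 0.988 for the ribosome, r = 0.934 and rho = 0.920 for slow fibre and r = 0.902 and rho = 0.916 for fast fibre genes, with permutation p = 1e-05 for each, 2e-05 after adjustment over 8 relations. Without the 2 arrays farthest from the median ceiling r was 0.988, 0.921 and 0.872. Within the higher 12 arrays r was 0.975, 0.858 and 0.909, and within the lower 12 it was 0.936, 0.593 and 0.578. As these lists hold abundant transcripts, their own signals may be part of the ceiling. A ceiling without the single-symbol probe sets of ribosomal proteins was computed for the ribosome list alone and is given further below. With the ceiling as a covariate the mean differences between morbidly obese and nonobese muscle became −0.01 for the ribosome, 0.17 for slow fibre, 0.10 for fast fibre and 0.07 for complexes II to IV, and none of these passed. The extracellular matrix list, not called in the deposited values (mean −0.07), was the 1 list that passed then, at −0.23 (adjusted p = 0.0235). That call used the preset correlation, and an estimated one was not run with the covariate. With the 2 sets of 12 arrays as a block the means of ribosome, slow fibre, fast fibre and complexes II to IV were −0.15, −0.13, −0.18 and −0.01. The ribosome list alone among them passed with the preset correlation (adjusted p = 3.9e-05), but not with an estimated correlation (adjusted p = 0.923). Among the 12 arrays with the higher ceiling the groups held 7 nonobese and 3 morbidly obese samples, and the lower 12 held only 1 nonobese sample, so that no comparison with nonobese was made there.

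**Figure D1:**
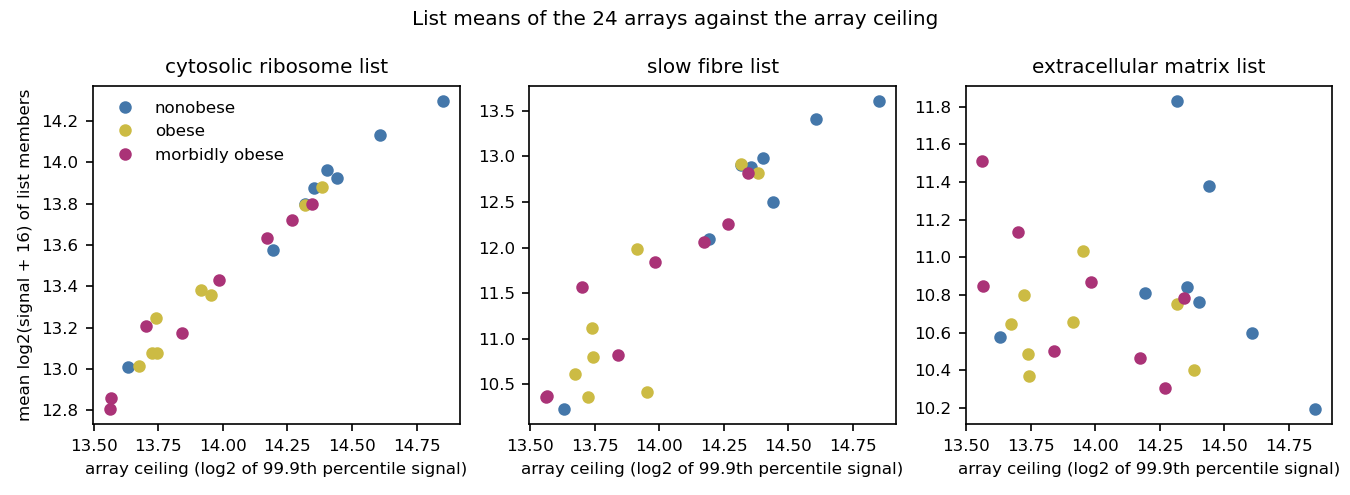
Mean log2(signal + 16) of the members of 3 gene lists (vertical axes) in each of the 24 arrays against the array ceiling, the log2 of the signal that 0.1% of its probe sets exceed (horizontal axis). Each point is 1 sample, coloured by group; the ribosome and slow fibre means follow the ceiling (r = 0.989 and 0.934), the extracellular matrix mean does not (r = −0.13).

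All 13 macrophage and myeloid markers had higher signals in morbidly obese muscle, with a mean log2 difference of 0.29 (adjusted p = 0.0258, and adjusted p = 0.757 with an estimated correlation). They included the complement components C1QA at 0.83 and C1QB at 0.36, lysozyme (LYZ) at 0.72 and the integrin ITGAM at 0.32. With the ceiling as a covariate the mean was 0.08 and the call was lost. It was also lost without morbidly obese replicate 4 (mean 0.17) or 5 (0.23) and without nonobese replicate 2 (0.18), 3 (0.29) or 8 (0.24). In the proteasome and atrophy list, 21 of 27 genes had higher signals, averaging 0.11 (adjusted p = 0.0159, and adjusted p = 0.757 with an estimated correlation), with PSMB6 at 0.37, PSMD1 at 0.30, PSMB4 at 0.25 and myostatin (MSTN), the inhibitor of muscle growth, at 0.64. With the ceiling as a covariate that mean was 0.05 and did not pass, nor did it, at 0.09, without nonobese replicate 3 or 5 or morbidly obese replicate 2 or 6. Under quantile normalization 8 lists passed with the preset correlation, 5 higher and 3 lower, and an estimated correlation was not run there. Newly called there, and higher, were complex I at 0.11 (adjusted p = 0.00336), ATP synthase at 0.13 (adjusted p = 0.00501) and the citric acid cycle at 0.12 (adjusted p = 0.0442), which in the deposited scaling averaged 0.01, −0.07 and 0.05. The ribosome list stayed lower there, at −0.20 (adjusted p = 3.1e-05). So did slow fibre at −0.88 (camera adjusted p = 0.00246) and fast fibre at −0.60 (camera adjusted p = 0.0477), unlike with the ceiling as a covariate.

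The fatty acid oxidation list had 11 of 23 genes with higher and 12 with lower signals in morbidly obese muscle (mean log2 difference 0.03, median −0.0039, adjusted p = 0.904). Its largest departures by p were ACACB at 0.39, ETFDH at 0.29, ACAA2 at 0.31 and ACADM at 0.31. Desaturation and fatty acid synthesis genes averaged 0.21 higher without passing (adjusted p = 0.329), with the citrate carrier SLC25A1 at 0.52, SCD at 0.94, SREBF1 at 0.29 and MLXIPL at 0.58. Of 25 genes of fatty acid partitioning fixed in advance, 22 were tested. CPT1B, read by 2 probe sets that also carry another symbol, and DGAT2 and GPAM, which have no probe set here, were not. None passed over all genes, and 1 passed when adjusted over the list alone. That gene was ACACB, the acetyl-CoA carboxylase whose malonyl-CoA restrains entry of fatty acids into mitochondria, at 12.005 ± 0.10 in morbidly obese against 11.62 ± 0.31 in nonobese samples (SD, n = 8), a log2 difference of 0.39 with SE 0.11 and higher than the nonobese mean in 8 of 8 samples (limma adjusted p = 0.0273 over the list alone and 0.451 over all genes). Its other 3 probe sets differed by 0.38, 0.17 and 0.09. Over the list alone ACACB no longer passed with the ceiling as a covariate (0.27, adjusted p = 0.268), with the mean of all its probe sets (0.25, adjusted p = 0.320) or with only the compared groups in the fit (adjusted p = 0.0812), nor without nonobese replicate 1, 2, 5 or 7 or morbidly obese replicate 1, 4 or 7 (differences from 0.32 to 0.38). The 2 sets of 12 arrays as a block ended its call as well. Its adjusted p ranged up to 0.530 over the alternatives. The largest difference among the fixed genes was that of SCD at 0.94 (SE 0.47), which did not pass. Others were ACADM at 0.31, LPL at −0.30, SREBF1 at 0.29, SLC2A4 at 0.23, INSR at 0.22 and PPARA at −0.19. The values were −0.17 for IRS1, −0.17 for UCP3, −0.17 for PDK4, 0.16 for FASN, −0.16 for CD36, 0.16 for PPARD, 0.14 for PLIN2, −0.13 for CPT2, 0.11 for DGAT1 and −0.11 for FABP3. For PPARGC1A, MLYCD, HADHA and ADIPOR1 they were −0.09, −0.08, 0.03 and 0.02.

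Markers of adipocytes averaged 0.26 higher in morbidly obese than in nonobese muscle (adjusted p = 0.487), with GPD1 at 0.62, ADIPOQ at 0.68, LPL at −0.30 and PLIN1 at 0.72, and GPD1 passed when adjusted over that list alone. The count of called genes was 1 in place of 0 with no filter on low values, where GRB14, an adaptor that inhibits the insulin receptor, was called among 11925 genes (adjusted p = 0.0188). GRB14, named after its values were seen, had a mean signal at the 38.9th percentile of probe sets and so lay just under the filter. Its log2 signal was 8.50 ± 0.46 in morbidly obese, 7.80 ± 0.40 in obese and 7.21 ± 0.29 in nonobese samples (SD, n = 8), a fold of 2.44 between the first and the last, and the lowest morbidly obese sample (7.92) exceeded the highest nonobese sample (7.51). Chance gives 1.9 genes of 11925 whose groups of 8 stand fully apart in this way, and 5 were found. With the ceiling as a covariate the GRB14 difference was 1.16 and did not pass (adjusted p = 0.343). The count was also 1 with the adipocyte markers as a covariate (VIM, −0.55) and 1 without morbidly obese replicate 4 (NNMT, −1.38), each time with a different gene.

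**Figure D2:**
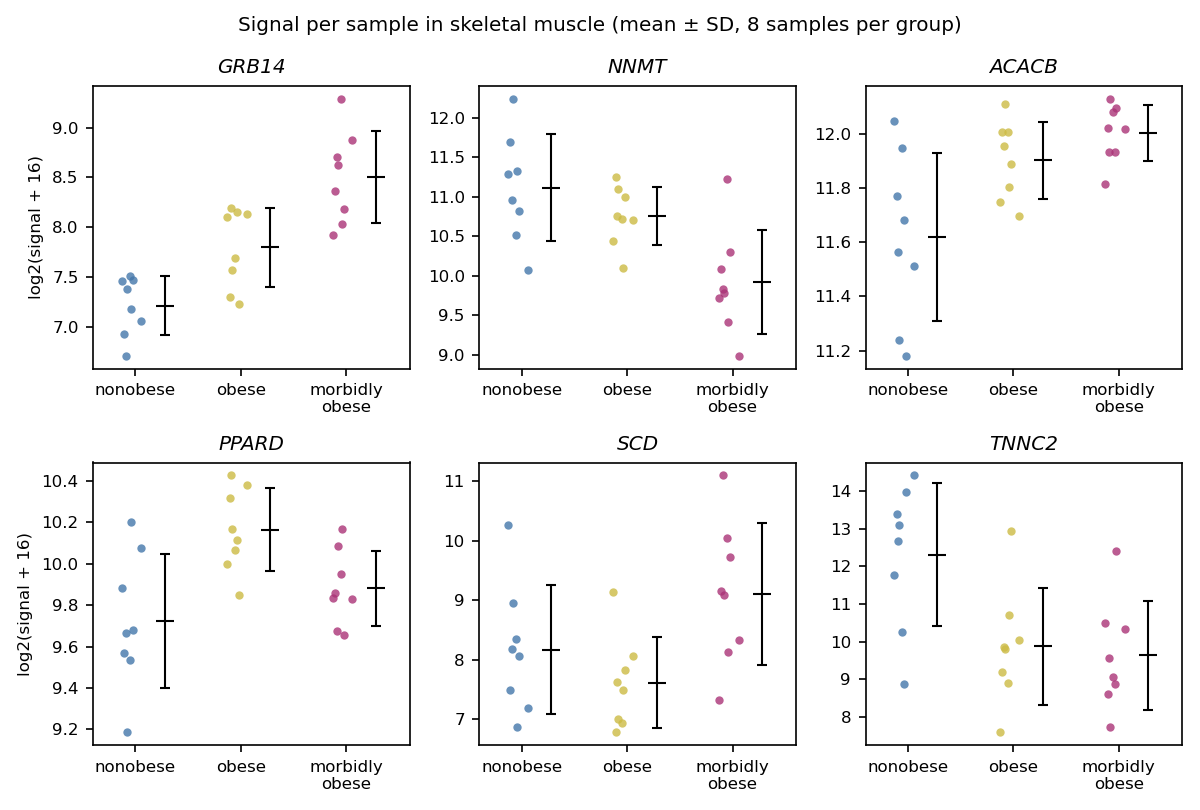
Log2(signal + 16) of 6 genes in each of the 24 samples by group, with the group mean and SD (n = 8) to the right of the points. GRB14 samples of the morbidly obese group all lie above 7.92 and nonobese samples below 7.51, while the groups overlap for NNMT, ACACB, PPARD, SCD and TNNC2.

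Obese muscle was then set against nonobese muscle. Contractile, ribosomal and glycolytic transcripts and those of respiratory complexes II to IV had lower signals in the obese group, as did genes of the extracellular matrix and fibroblast markers, while proteasome genes had higher signals by the list test with a preset correlation. None of these lists passed with an estimated correlation (lowest adjusted p = 0.123), and the matrix and fibroblast lists alone passed with the array ceiling as a covariate. ATP synthase and complex I genes were lower on average in the deposited values and higher under quantile normalization. The nuclear receptor PPARD, which activates genes of fatty acid oxidation, had a log2 signal of 10.2 ± 0.20 in obese against 9.72 ± 0.32 in nonobese samples (SD, n = 8), a fold of 1.36 (log2 difference 0.44, SE 0.12). All 8 obese samples lay above the nonobese mean. Its other 2 probe sets, which had lower signals, differed in the opposite direction by −0.64 and −0.19. Limma called 0 of 8180 genes (lowest adjusted p = 0.703), and 525 had an unadjusted p under 0.05, 294 higher and 231 lower, where chance alone gives 409. With the array ceiling as a covariate the count was 360, with 162 higher and 198 lower.

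Again none of the 20 genes with the smallest p passed. Those with higher signals had log2 differences of 0.38 for NDUFAF1, 0.54 for the flippase ATP9B, 0.59 for the elongation factor ELL, 0.44 for PPARD, 0.75 for NCKAP1, 0.38 for FBXW11, 0.40 for the chloride transporter CLCN4, 0.60 for GATAD2A, 0.40 for KHSRP and 0.41 for UBAP2. Those with lower signals had differences of −0.57 for the ribosomal protein RPL3, −0.51 for RUFY3, −0.998 for COX8A, −0.97 for the small heat shock protein HSPB1, −0.37 for ATP6V1G1, −0.36 for RPL35A, −2.44 for TNNC2, −0.45 for CSTF2, −0.44 for ACTB and −0.31 for HSPB8. After adjustment for the ceiling the differences of COX8A, HSPB1, TNNC2 and ACTB were −0.27, −0.37, −0.79 and −0.16, those of NCKAP1, RPL35A and HSPB8 were 0.48, −0.23 and −0.21, and that of RPL3 was −0.64. Another probe set of NCKAP1 differed by −0.02, and the others of KHSRP by −0.23 and 0.21. For RPL35A (0.50) and RUFY3 (0.07) a probe set under the filter level went the other way, while their remaining ones did not. The others of ATP9B, ELL, FBXW11, CLCN4, UBAP2 and ACTB kept the direction.

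Camera called 10 of the 33 lists with the preset correlation, 9 lower and 1 higher in obese muscle. Under quantile normalization 5 passed, 1 higher and 4 lower. None passed in the exact permutation test after adjustment (lowest adjusted p = 0.221). The ribosome list had 40 of 41 genes with lower signals, averaging −0.47 (adjusted p = 9.4e-31, and adjusted p = 0.123 with an estimated correlation), led by RPL3, RPL19 at −0.61, RPL11 at −0.55 and RPL24 at −0.42. All 11 slow fibre genes had lower signals, by −1.20 on average (adjusted p = 1.3e-09, and adjusted p = 0.123 with an estimated correlation), with ATP2A2 at −1.48, TNNI1 at −0.60, the slow troponin T TNNT1 at −2.35 and the myosin light chain MYL3 at −0.47. In the fast fibre list it was 12 of 13, averaging −0.997 (adjusted p = 4.5e-07, and adjusted p = 0.123 with an estimated correlation), with TNNC2, CASQ1 at −0.60, TNNT3 at −0.57 and MYL1 at −2.45. Adjusted for the ceiling, these 3 means were 0.01, 0.03 and −0.09, and none passed. Under quantile normalization they were −0.16, −1.03 and −0.80. All 3 stayed called there with the preset correlation (camera adjusted p = 1.6e-04, 1.9e-05 and 3.7e-04).

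Of the energy metabolism lists, 4 were called lower in obese muscle, while the citric acid cycle averaged 0.02, with 10 of 17 higher, and did not pass (adjusted p = 0.872). Of 23 genes of complexes II to IV, 20 had lower signals, with a mean of −0.28 (adjusted p = 9.7e-08, and adjusted p = 0.292 with an estimated correlation). Under quantile normalization that mean was −0.05 and the call was lost (camera adjusted p = 0.811). COX8A, at 12.8 ± 0.52 against 13.8 ± 0.55 (SD, n = 8), passed when adjusted over that list alone, and COX5B differed by −0.43, COX7C by −0.53 and COX7A1 by −0.77. ATP synthase genes averaged −0.14, with 13 of 15 lower (adjusted p = 1.1e-04, and adjusted p = 0.292 with an estimated correlation), but 0.07 under quantile normalization, and ATP5PO, ATP5PD, ATP5F1C and ATP5F1A differed by −0.39, −0.37, −0.24 and −0.25. Complex I genes averaged −0.06, with 19 of 28 lower (adjusted p = 0.0331, and adjusted p = 0.822 with an estimated correlation), but 0.04 under quantile normalization. That call was lost without nonobese replicate 5 (mean −0.04), nonobese replicate 1 or 2 or obese replicate 8 (−0.05 each), or obese replicate 1, 6 or 7 (−0.06 each). Of these genes, NDUFS3 differed by −0.28, NDUFA1 by −0.60, NDUFB2 by −0.26 and NDUFV1 by −0.20. Glycolysis and glycogen genes averaged −0.36, with a median of −0.16 and 17 of 24 lower (adjusted p = 0.00104, and adjusted p = 0.245 with an estimated correlation). The mean was −0.15 under quantile normalization, where the call was lost (camera adjusted p = 0.824). These genes included PGM1 at −0.49, aldolase A (ALDOA) at −3.15 (SE 1.25), LDHA at −0.60 and PFKM at −0.73. The means of these 4 lists adjusted for the ceiling were 0.03, −0.01, −0.01 and 0.00, and none passed.

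The extracellular matrix list had 25 of 31 genes with lower signals in obese muscle, averaging −0.23 (adjusted p = 3.2e-05, and adjusted p = 0.684 with an estimated correlation). Without nonobese replicate 6 the mean was −0.09 and the call was lost (adjusted p = 0.108). The per-sample list mean was 10.6 ± 0.22 in obese and 10.9 ± 0.51 in nonobese samples (SD, n = 8), which did not separate in the exact permutation test (p = 0.279). Decorin (DCN) differed by −0.41, COL15A1 by −0.32, COL5A2 by −0.70 and TGFB1 by −0.29. Fibroblast markers averaged −0.18, with 9 of 12 lower (adjusted p = 0.0122, and adjusted p = 0.721 with an estimated correlation). They shared DCN, COL1A1 (−0.68) and COL3A1 (−0.43) with the matrix list and also held gelsolin (GSN) at −0.21. The fibroblast call was lost without nonobese replicate 6 (mean −0.06) or 5 (−0.12) and without obese replicate 1 (−0.12), 4 (−0.14) or 7 (−0.13), and without nonobese replicate 2 the mean was −0.27. Unlike the lists above, these did not shrink with the ceiling as a covariate, where the means were −0.38 for the matrix (adjusted p = 1.9e-08) and −0.28 for fibroblast markers (adjusted p = 0.0121). The fibroblast call was lost under quantile normalization (mean −0.14, adjusted p = 0.199). In the proteasome and atrophy list, 25 of 27 genes had higher signals, averaging 0.12 (adjusted p = 0.00215, and adjusted p = 0.364 with an estimated correlation), with PSMB6 at 0.35, PSMB7 at 0.24, PSMD12 at 0.17 and PSMA1 at 0.17; with the ceiling as a covariate the mean was 0.07 and did not pass.

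Fatty acid oxidation genes averaged −0.01 in obese against nonobese muscle, with 11 of 23 higher (adjusted p = 0.727), and CRAT, ACACB, HADHB and ACADL differed by −0.30, 0.28, −0.33 and 0.32. Desaturation and synthesis genes averaged −0.05 (adjusted p = 0.821), with SLC25A1 at 0.40, MLXIPL at −0.55, SCD at −0.56 and SREBF1 at 0.23. Among the 22 fixed genes none passed over all genes and PPARD passed when adjusted over the list alone (limma adjusted p = 0.0320). It did not with the ceiling as a covariate (0.35, adjusted p = 0.448), nor without nonobese replicate 1, 4, 5, 6 or 7 or obese replicate 2, 5, 6 or 7 (differences from 0.36 to 0.44), and its adjusted p ranged up to 0.573 over the alternatives. The other fixed genes, in order of size, began with SCD at −0.56 (SE 0.47), CPT2 at −0.47, PPARA at −0.30, UCP3 at −0.29, ACACB at 0.28, LPL at −0.27, SLC2A4 at 0.26, FABP3 at −0.25, ACADM at 0.25, SREBF1 at 0.23, CD36 at −0.22, DGAT1 at 0.21, MLYCD at 0.20 and PLIN2 at 0.20. The remaining fixed genes PDK4, INSR, PPARGC1A, IRS1, HADHA, FASN and ADIPOR1 differed by −0.13, 0.12, −0.12, −0.10, −0.09, −0.08 and −0.03. Over both comparisons with nonobese muscle and that between the obese groups, 2 fixed genes were called when adjusted over the list alone; with the mean of all probe sets of a gene, with only the groups compared in the fit, or with the ceiling as a covariate, 0 were.

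The obese groups were also compared directly. Morbidly obese muscle had a higher signal for SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, than obese muscle, and higher signals over the lists of the extracellular matrix and of complex I. Both lists passed with a preset correlation and neither with an estimated correlation (adjusted p = 0.866 each). SCD was at 9.11 ± 1.19 in morbidly obese and 7.61 ± 0.77 in obese samples (SD, n = 8), a fold of 2.84 (log2 difference 1.504, SE 0.47), with 7 of 8 morbidly obese samples above the obese mean. In nonobese samples it was 8.17 ± 1.08. The 4 SCD probe sets differed by 1.504, 1.79, 0.72 and 0.65, and all but the first lay under the filter on low values. SCD did not pass over all genes, where limma's lowest adjusted p in this comparison was 0.99999, or when adjusted over the 22 fixed genes alone (adjusted p = 0.0752), and passed when adjusted over the desaturation and synthesis list alone (adjusted p = 0.0410). No gene passed in this comparison, and 264 of 8180 had an unadjusted p under 0.05, 124 higher and 140 lower.

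The 10 genes with higher signals and the smallest p, none of which passed, had log2 differences of 0.50 for the chaperonin subunit CCT5, 0.90 for MINDY3, 0.82 for CD2BP2, 0.44 for UNC13B, 0.45 for CSTF2, 1.504 for SCD, 0.51 for PLA2G12A, 0.48 for RBM28, 0.62 for PLXDC1 and 0.31 for smoothelin (SMTN). The 10 with lower signals had differences of −0.64 for DNAI4, −0.58 for AGAP2, −0.35 for the tubulin TUBA1C, −0.54 for AUTS2, −0.39 for GEMIN4, −0.49 for RPGRIP1, −0.84 for NNMT, −0.46 for the GTPase GEM, −0.41 for ZNF205-AS1 and −0.41 for the splicing factor SFPQ. Another probe set of PLXDC1, at a like level, differed by −0.03, and that of CD2BP2, under the filter level, by −0.12. The others of SMTN, AGAP2 (−0.05), TUBA1C, GEMIN4, NNMT and SFPQ kept the direction. Among the fixed genes the differences after SCD were 0.33 for CPT2, −0.28 for PPARD, −0.28 for MLYCD, 0.24 for FASN, 0.15 for FABP3, 0.12 for HADHA, 0.11 for UCP3, −0.11 for DGAT1, 0.10 for PPARA, 0.10 for ACACB and 0.10 for INSR. For IRS1, SREBF1, ACADM, PLIN2, CD36, ADIPOR1, PDK4, PPARGC1A, SLC2A4 and LPL they were −0.08, 0.07, 0.06, −0.06, 0.06, 0.05, −0.05, 0.03, −0.03 and −0.02.

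Desaturation and fatty acid synthesis genes averaged 0.26 higher in morbidly obese than in obese muscle, with 9 of 12 higher, and did not pass (adjusted p = 0.140). The transcription factor MLXIPL, which drives lipogenic genes in response to carbohydrate, differed by 1.13 (SE 0.41), FADS3 by −0.39 and ELOVL5 by 0.30. Camera called 2 of the 33 lists with the preset correlation, and none passed in the exact permutation test after adjustment (lowest adjusted p = 0.895). In the extracellular matrix list 22 of 31 genes had higher signals, averaging 0.16 (adjusted p = 0.0207, and adjusted p = 0.866 with an estimated correlation), with COL15A1 at 0.41, SPARC at 0.47, COL1A2 at 0.46 and TGFB1 at 0.24. That call was lost without morbidly obese replicate 4 (mean 0.06) or 5 (0.11) and without obese replicate 4 (0.12), 7 (0.14) or 8 (0.16). Complex I genes averaged 0.07, with 23 of 28 higher (adjusted p = 0.0278, and adjusted p = 0.866 with an estimated correlation), and NDUFB8, NDUFV1, NDUFA9 and NDUFS3 differed by 0.24, 0.23, 0.21 and 0.20. The complex I call was lost without morbidly obese replicate 2 (mean 0.03), 3 (0.05) or 8 (0.07) and without obese replicate 6 (0.07), 7 (0.07) or 8 (0.06). It was also lost with the 2 sets of 12 arrays as a block (0.06, camera adjusted p = 0.0953). The ribosome list was newly called lower there (−0.11, camera adjusted p = 0.00527, and 0.957 with an estimated correlation). Fatty acid oxidation genes averaged 0.04 (adjusted p = 0.364), with ACADL at −0.49, ETFDH at 0.25, ACAA2 at 0.31 and MLYCD at −0.28.

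Adipocyte markers averaged 0.22 higher in morbidly obese than in obese muscle without passing (adjusted p = 0.140), with GPD1 at 0.38, FABP4 at 0.35, CIDEC at 0.24 and PLIN1 at 0.30. Across the 24 samples their list mean correlated with SCD at r = 0.579 (permutation p = 0.0032) and rho = 0.468 (p = 0.023), 0.0043 and 0.031 after adjustment over 8 relations. It was r = 0.399 without the 2 samples farthest from the median of the markers, 0.395 within the higher 12 arrays and 0.740 within the lower 12. SCD did not follow the array ceiling (r = −0.09, rho = 0.00, permutation p = 0.66 and 1). The call of complex I was lost under quantile normalization, where its mean was 0.07 and the count of lists called was 1. The matrix list averaged −0.06 among the 12 arrays with the higher ceiling, which held 3 morbidly obese and 2 obese samples.

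**Figure D3:**
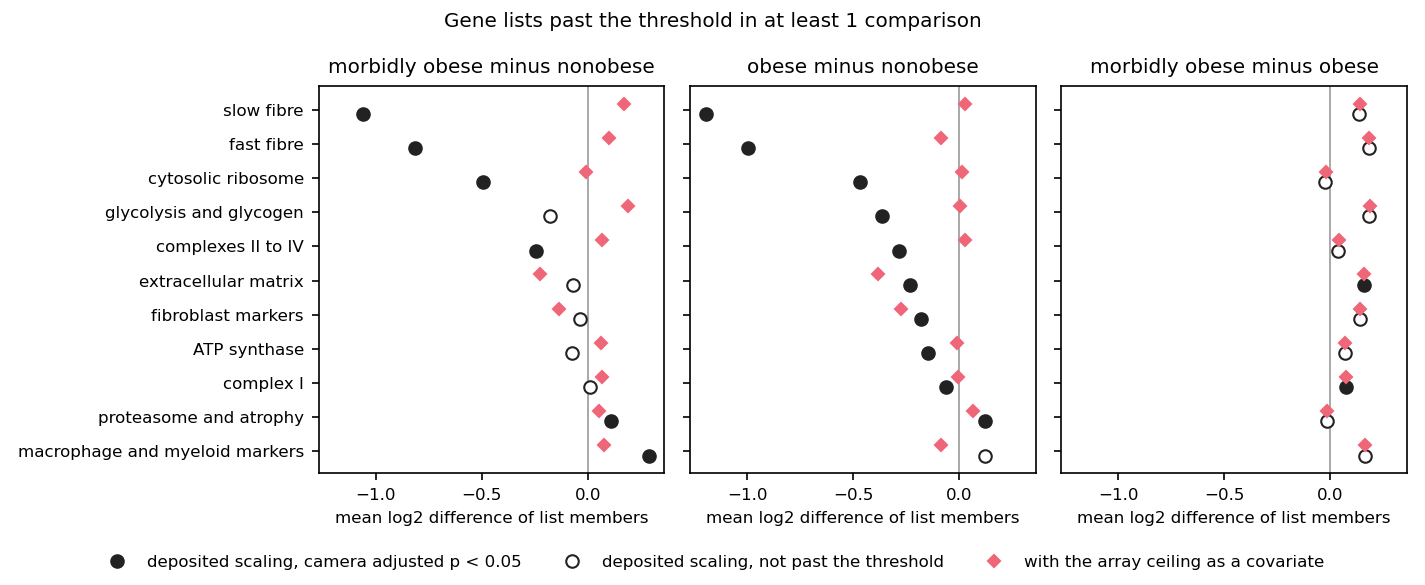
Mean log2 difference of the members (horizontal axes) of the 11 gene lists that passed in at least 1 comparison, for each of the 3 comparisons. Filled circles passed with camera's preset correlation and open circles did not; diamonds give the mean with the array ceiling as a covariate, close to 0 for ribosome (−0.01 and 0.01 against nonobese), and further from 0 for the extracellular matrix in obese against nonobese muscle (−0.38).

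Over all 3 groups together, limma's F test called 0 of 8180 genes (lowest adjusted p = 0.759), with 483 genes at an unadjusted p under 0.05. The log2 differences of morbidly obese and of obese muscle against nonobese muscle correlated across genes at r = 0.715, with a covariance of 0.0401 and the same sign for 71.6% of genes. Genes are not independent replicates, and both comparisons share the nonobese samples. Unchanged groups were drawn from the deviations of all samples from their group means, with a drawn reference group shared by both contrasts. They gave a median r of 0.497 (from 0.280 to 0.720 over 100 draws) and a median covariance of 0.0207 (from 0.0094 to 0.0403). With the nonobese samples split 4 and 4 over the 35 possible splits, the correlation had a median of 0.252 and a range from 0.118 to 0.336. The observed values lay within the simulated range but close to its upper end, well above the simulated medians.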

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

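Tests chosen only after the result was seen were those of the ribosome list beyond the ceiling, of the control RNA against a ceiling without control probe sets, of RNA quality, of SCD against the ceiling and over its other probe sets, and of the matrix list against the ceiling and for genes that vary together.

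The most abundant transcripts were lower in both obese groups than in nonobese muscle: among the top 5% of genes by level, 74.6% were lower in morbidly obese and 74.3% in obese samples. This held for the top 5% only. From the 90th to the 95th percentile 35.9% and 35.5% were lower, and from the 50th to the 90th 37.9% and 39.6%. The median correlation with the ceiling was 0.474 in the top 5% and −0.149 from the 90th to the 95th percentile. A candidate explanation is the brightness of the hybridized array. The cre control RNA, which carries no patient RNA, followed a ceiling computed without control probe sets within groups at r = 0.9796 (permutation p = 1e-05, the smallest they can give), and the weaker control bioB at r = 0.427. Cre itself differed from nonobese by −0.345 in morbidly obese (exact permutation p = 0.046) and by −0.349 in obese samples (exact permutation p = 0.030), both unadjusted. The lower signal near the ceiling was thus not confined to patient transcripts. Cre had a mean log2 signal of 13.85, close to the ceiling, and bioB one of 9.25. The bioC and bioD control probe sets correlated with the ceiling across arrays at r from 0.139 to 0.741. As cre lies near the ceiling, it cannot tell a dimmer array as a whole from a change of the brightest signals alone. Lower ribosomal protein expression beyond the ceiling stays open. The list difference between morbidly obese and nonobese was −0.49 (SE 0.18). It was −0.0129 (SE 0.036) with a ceiling without single-symbol ribosomal protein probe sets as a covariate. Probe sets with several symbols were not removed from that ceiling, and no list test was run with it. With the full ceiling as a covariate the call was lost (camera adjusted p = 0.874). The mean was −0.15 (SE 0.11) with the 2 sets of 12 arrays as a block and −0.20 under quantile normalization. Both were called with the preset correlation, and the former not with an estimated one. Slow and fast fibre genes also stayed lower under quantile normalization, at −0.88 and −0.60, and stay open as well. RNA quality stays open too: within groups the log2 ratio of 3′ to 5′ signals of ACTB correlated with the ceiling at r = −0.8205 and that of GAPDH at r = 0.195. The 3′ and 5′ signals themselves followed the ceiling, at r = 0.773 and 0.925 for ACTB and 0.913 and 0.711 for GAPDH. The ratios therefore cannot separate RNA quality from the ceiling. The ACTB ratio was higher than in nonobese by 0.16 in morbidly obese and 0.23 in obese samples (adjusted p = 0.409 and 0.285), the GAPDH ratio lower by 0.95 and 0.81 (0.4995 and 0.545). The 3′, middle and 5′ GAPDH signals differed from nonobese by −2.5001, −4.28 and −1.54 in morbidly obese samples. In obese samples they differed by −2.9968, −3.39 and −2.07. With SE from 1.12 to 1.32, none passed limma's test (adjusted p from 0.0628 to 0.379). Differences of a like size were given above for MB, ATP2A1 and ALDOA, and a cause shared with GAPDH was not tested. Within each group the arrays with the higher ceiling had the lowest title numbers. Neither obesity itself nor the order of processing was tested as the reason for the different ceilings.

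SCD was higher in morbidly obese than in obese muscle by 1.504 (limma SE 0.47). An effect of the ceiling is argued against, as the ceilings of these groups differed by −0.0017, which at the slope of SCD on the ceiling within groups gives 0.000394 (SE 0.037) of the difference, and so is a fault of a single probe set, as the other 3 probe sets differed by 1.052 on average (SE 0.45). Adipose tissue in the samples may contribute, since SCD correlated with the adipocyte markers, and with these as a covariate the difference was 1.233 (SE 0.44), past the bound set against it, 1.0, by less than its SE, where under 0.75 was set for it. Among the adipocyte markers, ADIPOQ was at 10.9 ± 0.96 in morbidly obese and 10.6 ± 0.61 in obese samples and FABP4 at 12.7 ± 0.54 and 12.3 ± 0.41, while LEP, under the filter and so not among the markers averaged, was at 7.50 ± 1.76 and 5.73 ± 0.55 (SD, n = 8). Obesity itself stays open as an untested biological explanation.

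Extracellular matrix genes were lower in obese than in nonobese muscle (mean difference −0.23, SE 0.20). Without nonobese replicate 6 the difference was −0.09 (SE 0.17) and the list was not called, so that much of the pattern rests on 1 sample. The ceiling is argued against as the source over all samples, since with it as a covariate the difference was −0.3842 (SE 0.22), further from 0 than without the covariate. Without that sample it was −0.24 (SE 0.19), also further from 0 than without the covariate, but the SE is too wide to decide by the same rule. Matrix genes that vary together from sample to sample may account for the call, as the exact permutation test of the list mean gave an adjusted p of 0.7085. A lower share of fibroblasts cannot be told apart from lower matrix expression, because the 7 fibroblast markers outside the matrix list differed by −0.0692 on average, with an SE of 0.158, between the outcomes set for it (−0.23 or lower) and against it (above −0.05). Obesity stays open as an untested biological explanation.

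Other splits of the samples, 100 for each comparison with the real one included, gave as many genes at an unadjusted p under 0.05 in 9 for morbidly obese against nonobese (real 610, highest other 807), 18 for obese against nonobese (525 and 1185) and 85 for morbidly obese against obese (264 and 962). For the F test it was 22 (483 and 775). As many lists were called in 46 (6 and 14), 11 (10 and 14) and 78 (2 and 16). Chance cannot be excluded for any of these counts. Some other splits between the obese groups gave several times the real counts, which may reflect a structure of the samples or, for lists, genes that vary more together than the preset correlation allows; these were not told apart by a test. At an adjusted p under 0.05 the real splits called 0 genes, and 4, 6, 6 and 5 of the other splits called any gene in the 3 comparisons and the F test.

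In 29 of 333 groups of 8 values, 1 sample stood apart from the rest, where chance gives 16.7. These groups share samples and genes that vary together, and the excess was not tested. The ratio is the gap to the nearest sample over the group's range, with a critical value of 0.526. Among nonobese samples the lowest stood apart for the lists of fatty acid oxidation (0.607), the citric acid cycle (0.532), glycolysis (0.705), slow fibre (0.551), fast fibre (0.619) and T cell markers (0.565). It also stood apart for SLC29A2 (0.604), ACTB (0.677), COX8A (0.586) and the first principal component (0.548), and the highest for NCKAP1 (0.573). On the first principal component the lowest nonobese sample was replicate 8, the only nonobese array with the lower ceiling. Among obese samples the highest stood apart for the insulin signalling list (0.534), COX8A (0.658) and GEM (0.601). The lowest did for adipocyte markers (0.554), smooth muscle markers (0.553), FBXW11 (0.616) and CCT5 (0.528). Among morbidly obese samples the highest stood apart for the lists of inflammation (0.647), interferon response (0.692) and metallothionein (0.534), and for CACYBP (0.574), INSR (0.561), GATAD2A (0.547) and RBM28 (0.603). The lowest did for LPL (0.532), PLIN2 (0.535), FASN (0.535) and GEM (0.656).

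Of the control probe sets, tested apart from the genes, 2 differed between obese and nonobese muscle in limma's test. AFFX-M27830_M_at was higher by 1.22, at 9.99 ± 0.18 against 8.76 ± 0.52 (SD, n = 8), with an adjusted p of 0.00299. The probe set AFFX-M27830_5_at, which shares its name, differed by 0.05 (limma adjusted p = 0.787). AFFX-BioDn-3_at differed by −0.334, at 12.97 ± 0.22 against 13.31 ± 0.21, with an adjusted p of 0.0368; it follows the array ceiling (r = 0.741), which was lower by 0.42 in obese samples.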

How the results depend on the processing

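The alternatives chosen after seeing the data were those with the array ceiling, the 12 higher or lower arrays, and the 5% most abundant genes left out. The count of 0 genes held under all alternatives run for obese against nonobese, for morbidly obese against obese and for the F test. Where a count or a direction changed, the cause was not tested unless given. For morbidly obese against nonobese 1 gene was called with no filter, 1 with the adipocyte markers as a covariate, and 0 to 1 with a sample left out (1 without morbidly obese replicate 4). The 6 lists called there became 0 with an estimated correlation, 1 with the ceiling as a covariate and 1 with the 2 sets of 12 arrays as a block, and 4 to 7 with a sample left out.

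The 10 lists called for obese against nonobese became 5 under quantile normalization, 0 with an estimated correlation, 2 with the ceiling as a covariate, 1 with the block of arrays, 2 among the 12 higher arrays (fewer samples) and 4 without the 5% most abundant genes, and 8 to 11 with a sample left out. The 2 lists called between the obese groups became 1 under quantile normalization, 0 with the mean of all probe sets, 1 with the replicate block, 1 without the 2 samples with another title suffix, 0 with an estimated correlation, 1 among the higher and 6 among the lower 12 arrays. The lower arrays held 1 nonobese sample, so no other comparison was run there. Leaving out 1 sample gave 0 (obese replicate 7 or 8) to 5 lists (obese replicate 1, 2 or 5). It gave 4 without obese replicate 3 and 1 without obese replicate 4 or 6 or morbidly obese replicate 2 or 5.

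The 2 genes of fatty acid partitioning called over their own list became 0 with the mean of all probe sets, 0 with only the 2 groups compared, 0 with the ceiling as a covariate, 0 with the block of arrays and 0 among the higher arrays. They became 1 with the replicate block, 1 with the GAPDH ratio as a covariate, 1 with the adipocyte markers and 1 without the 2 samples with another suffix. Leaving out 1 sample gave 0 (nonobese replicate 1, 5 or 7) to 4 (nonobese or morbidly obese replicate 3). It gave 1 without nonobese replicate 2, 4 or 6, obese replicate 2, 5, 6 or 7, or morbidly obese replicate 1, 4 or 7. The correlation of the contrasts, 0.715, was 0.351 among the higher 12 arrays and 0.671 to 0.783 with a sample left out.

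Means of lists called with the deposited processing or with the alternative changed sign as follows, and lists called with neither did in 306 cases. Quantile normalization gave ATP synthase 0.134 in morbidly obese and 0.0679 in obese against nonobese, and complex I 0.0395 in obese. The ceiling as a covariate gave, for morbidly obese, complexes II to IV 0.0651, slow fibre 0.171 and fast fibre 0.0980, and for obese, complexes II to IV 0.0258, glycolysis 0.00285, slow fibre 0.0297 and ribosome 0.0129. The block of arrays gave complexes II to IV 0.00792 in obese. The higher arrays gave macrophage markers −0.0409 in morbidly obese against nonobese and the matrix −0.0579 between the obese groups. Without the most abundant genes complexes II to IV were at 0.0891 and 0.0321. Other values of single genes kept their call and direction in 5051 cases, passed newly in 2 and moved in 9; lists kept theirs in 4006, lost the call in 103, gained it in 49 and moved in 9. The title numbers were not taken to pair the samples. After removal of group means, 8 of 24 pairs with the same number correlated above 0.1 (median 0.033, highest 0.373). Of the 24 samples, 8 correlated best with their own number. The counts that chance gives were not computed, so a structure shared by some title numbers is not excluded. This is a hint from the data and not the design. Without detection calls, the signal over background of weak probe sets limits what can be said of them.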

Other observations

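The tests of GRB14, chosen after its values were seen, and those with the array ceiling were not planned; the others were.

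Heat shock genes were not called as a list in any comparison. In obese against nonobese muscle the 16 measured genes averaged −0.13 with a median of 0.05 (camera adjusted p = 0.0990), and with the ceiling as a covariate the mean was −0.0033. Small heat shock proteins of muscle were among the members with the smallest p, HSPB1 at −0.97, HSPB8 at −0.31 and the crystallin CRYAB at −0.74, together with HSP90AB1 at −0.49, and each passed when adjusted over the list alone. In the triglyceride and lipid droplet list, which averaged 0.00 in morbidly obese against nonobese muscle with a median of 0.05 (adjusted p = 0.952), the triglyceride lipase PNPLA2 differed by −1.05 and the droplet protein PLIN3 by −0.15. GPD1, also a member of the adipocyte markers, differed by 0.62. Insulin signalling genes averaged 0.08 (adjusted p = 0.604) in morbidly obese and 0.09 (adjusted p = 0.462) in obese against nonobese muscle. The regulatory subunit PIK3R1 differed by 0.56 and 0.50 and the receptor substrate IRS2 by −0.48 and −0.24, and none of these passed.

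The cell type lists that follow were not called. T cell markers averaged 0.23 higher in morbidly obese than in nonobese muscle (adjusted p = 0.329), with CD8A at 0.73 and CD2 at 0.33. Smooth muscle and pericyte markers averaged −0.18 in morbidly obese against obese muscle (adjusted p = 0.146), with ACTA2 at −0.41 and MYH11 at −0.91. Endothelial markers averaged 0.04, 0.03 and 0.02 in the 3 comparisons. The means of red cell markers differed in direction. The haemoglobin gene HBB was at 13.7 ± 0.48 in nonobese, 13.4 ± 0.48 in obese and 12.9 ± 0.77 in morbidly obese samples (SD, n = 8), and AHSP went from 8.44 ± 0.22 in nonobese to 8.29 ± 0.34 in morbidly obese. In contrast, HBD went from 9.05 ± 0.81 in nonobese to 9.31 ± 0.87 in morbidly obese, CA1 from 8.78 ± 0.59 to 8.96 ± 0.29, ALAS2 from 5.68 ± 0.70 to 6.07 ± 0.72 and SLC4A1 from 6.70 ± 0.34 to 7.01 ± 0.26, the last 2 under the filter. In obese samples HBD was at 8.84 ± 0.42 and CA1 at 8.58 ± 0.45, both lower than in nonobese.

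GRB14, left out by the filter on low values, differed between obese and nonobese muscle by 0.59 (exact permutation p = 0.0070) and between morbidly obese and obese muscle by 0.70 (exact permutation p = 0.0065), both unadjusted. Between morbidly obese and nonobese muscle the exact permutation p was 0.000155, the smallest that 8 against 8 can give. It has 1 probe set.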
